A study of Homo sapiens with 10 samples.

How the data were processed

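Poly(A)-selected RNA from PC9 cells, a human lung adenocarcinoma line with an activating EGFR mutation, was sequenced in 10 libraries. Per the labels' protocols, RNA was purified on columns, had an integrity number of at least 9 and went into TruSeq-type mRNA libraries. The libraries fall into 3 naive (untreated) libraries, 6 libraries from cells released from gefitinib, an EGFR kinase inhibitor, after 9 days on drug, and 1 library of an untreated PC9-derived clone called clone 4. Replicate numbers follow the order of deposition and pair nothing. Naive replicate 1 had been grown for 13 weeks without drug and naive replicate 2 for 2 weeks, while naive replicate 3 is labelled only as never treated. Released replicates 1 to 6 were taken 13, 14, 1.5, 2, 5 and 6 weeks after release. For released replicate 3 the title gives 1.5 weeks and the treatment label gives 15 weeks, so 1.5 was used and 15 tried as an alternative. Nothing in the labels says that libraries of a group came from independently treated cultures, so p-values measure the spread between these libraries.

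The deposited table holds raw gene counts, whole numbers that were not normalized, for 26364 gene symbols and 10 libraries. Per the submitters' processing notes, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3 were used with the hg19 genome build; the role and order of each tool are not given in the sources used here, and neither is the strand setting. The other part of the table is a non-negative signal per gene that the authors headed as DESeq2 normalized counts, and dividing the deposited counts by it gave 1 constant per library. Size factors recomputed from the counts of all 10 libraries matched those constants. All tests used the raw counts, and the normalized columns served only for that check. All 20 per-sample columns were matched to samples by name. Of the symbols, 23795 are current names, 1466 are older names and 1103 were not matched in the NCBI RefSeq gene table of GRCh38.p14. That table was used for names, gene types and the order of neighbouring genes, and no coordinates are given because its build differs from hg19.

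Total counts ran from 12.8 M to 15.3 M (M, megacounts) in the released libraries and from 14.45 M to 14.75 M in the naive ones, and clone 4 had 19.19 M. At that depth 1 count is under 0.1 CPM (counts scaled to a common library size), so low genes rest on few counts. For named genes with a group mean under 1 CPM the raw counts per library are given where that group is compared, since the sizes of such changes are uncertain. Counts were compared between every pair of libraries. The closest pair differed with a chi-square of 2.68 per degree of freedom, above sampling noise, so each library was counted once.

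Genes were tested with the quasi-likelihood test of edgeR 4.0.16 with robust dispersion, TMM normalization and the filterByExpr filter in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is called higher or lower, or said to rise or fall, when it passes that threshold. Released against naive used 6 and 3 libraries. A second fit put the 9 libraries into naive, early (1.5 and 2 weeks), middle (5 and 6 weeks) and late (13 and 14 weeks) groups, and gave each period against naive and late against early. Another fit regressed the 6 released libraries on log2 weeks, so that its slopes are log2 change per doubling of time. The standard error (SE) given beside a log2 fold change is that change divided by the square root of the F statistic. CPM values are TMM-scaled and given as mean ± SD.

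Gene lists were fixed before the data were examined, 32 in all, covering receptor signalling, cell state, lineage, metabolism, stress and other cell types. The 29 with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and a prior count of 2, again with the correlation estimated per list, and with fry. Members past the gene threshold are counted after adjustment over all genes and adjusted over the list alone. The named genes follow a rule set in advance. For released against naive they are the 8 largest rises and 8 largest falls among called genes with a mean of at least 2 CPM and no overlap between groups, up to 2 called members of each list by smallest p, and 9 receptor and adaptor genes whatever their result (IRS1, IRS2, INSR, IGF1R, EGFR, ERBB2, ERBB3, MET and AXL). For the other tests they are the 5 largest rises and falls among called genes with at least 2 CPM, of which the text names some and 1 is not reported here, and for clone 4 the 6 largest on each side that lay outside the range of the other 9 libraries. Other members of the lists are named as examples, and those were not refitted with libraries left out.

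Clone 4 has 1 library, so it has no test and no replicate check. Its derivation, and whether it was selected for a drug response, are not known from the labels, so what its direction or its use as a naive library means is open. Its log2 ratio to the mean of the naive libraries is given, and list medians are placed among 10000 random lists of equal size matched on mean expression. Where clone 4 had no count for a gene, a fold is computed against a floor of 3 counts in that library and is a lower bound. With 1 to 3 counts the ratio has an exact Poisson interval at 95%, which covers counting error only.

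Neighbouring genes were compared in windows of 40 tested genes in genomic order, moved in steps of 5, and the largest absolute window median was set against 1000 shuffles of the gene order. Of the genes tested for released against naive, 92.0% could be placed.

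The tests were checked on simulated counts drawn from the real means with 200 genes changed. For released against naive, 50.7% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 92.4% of those changed 4-fold were recovered among 13282 genes, and 7.05% of the calls were false. For late against early the shares were 23.9%, 59.7% and 84.8% among 13507 genes. In simulated lists, the list raised on purpose was recovered and 0 of 200 unchanged lists were called. Simulated genes were drawn independently, so this check does not cover lists whose members vary together. The interferon, proliferation and ribosomal lists had estimated correlations of 0.190, 0.361 and 0.939 in released against naive. A stretch of 40 neighbouring genes raised by 0.3 on the log2 scale was found by the window scan.

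Alternatives were DESeq2 1.42.0, size factors in place of TMM, no filter on low counts, an added size threshold of 1 on the log2 scale, each library left out in turn, clone 4 counted as naive, the mean of the 3 periods, only the libraries of weeks 2 and 13 with and without week as a block, linear weeks, and 15 weeks for released replicate 3. Leaving out naive replicate 3 and released replicate 3 together was added after the data were seen, as was setting early and late release against single naive libraries (log2 CPM with a prior count of 2). Mitochondrially encoded genes were not analysed here.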

Results

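The series compared naive PC9 cells with PC9 cells that had been treated with gefitinib for 9 days and then grown without drug for 1.5 to 14 weeks. Its title concerns IRS1, an adaptor of the insulin and IGF receptors, and the probability that cells persist under EGFR inhibition. Gene expression was measured by poly(A) RNA sequencing in 3 naive libraries, 6 released libraries and 1 library of an untreated derived clone. Total counts lay between 12.8 M and 15.3 M (M, megacounts) in the naive and released libraries and at 19.19 M in clone 4.

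The released libraries lay apart from the naive ones on the first principal component, which held 48.1% of the variance. Naive replicate 3, the library with no week in its label, stood apart from every other library. Its root mean square log2 difference was 0.54 from naive replicate 1 and 0.56 from naive replicate 2, which differed from each other by 0.29. It lay outside the range of all other libraries for 6431 of 11740 expressed genes. The closest pair were the released libraries at 1.5 and 2 weeks, at 0.25.

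**Figure D1:**
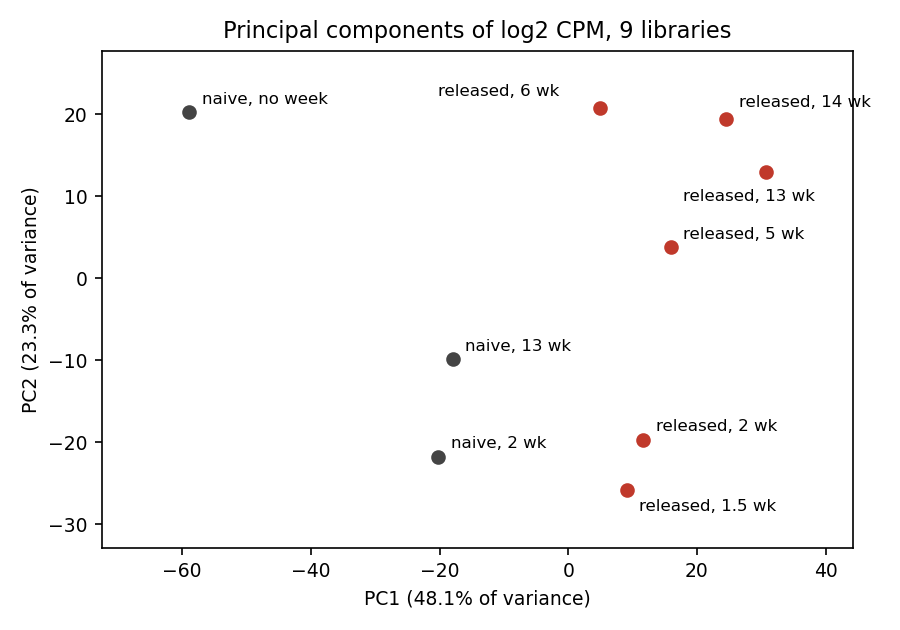
First and second principal components of log2 CPM for the 3 naive (grey) and 6 released (red) libraries, with the percent of variance on each axis (48.1% and 23.3%) and the weeks from the labels beside each point. All released libraries have positive PC1 values and all naive libraries negative ones, and the naive library without a week lies farthest out at -58.9.

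Among the largest rises, TSPYL5, a member of a nucleosome assembly protein family, went from 5.34 ± 0.485 CPM in naive (n = 3) to 24.0 ± 4.05 CPM in released libraries (n = 6). ZNF469, a zinc finger protein gene, went from 4.75 ± 2.41 to 22.3 ± 1.93 CPM. The log2 fold changes were 2.15 (SE 0.16, edgeR adjusted p = 0.00013) for TSPYL5 and 2.22 (SE 0.27) for ZNF469. OLR1, a receptor for oxidized LDL, rose by 2.86 from 3 to 15 counts per naive library, KCNJ12, a potassium channel, by 1.97, INHBA, an activin subunit, by 1.77, and MUC4, a membrane mucin, by 1.76. RPS6KL1 rose by 2.00. The largest rise, 3.62 (SE 0.39), belonged to OSTCP1, a transcribed pseudogene whose reads can be shared with its parent gene, so its level is uncertain.

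The falls were larger and more numerous. AOC1, the diamine oxidase, had a log2 fold change of -4.89 (SE 0.54), and the gel-forming mucins MUC5AC and MUC6 had -3.55 and -3.46. AOC1 had 0 to 6 counts per released library and MUC5AC 6 to 17, so the sizes of their falls are uncertain. FGFBP1, a carrier of fibroblast growth factors, had -3.12, KRT13, a keratin of stratified epithelia, -3.01, FAM167A -2.83, and CCAT1, a long noncoding RNA, -2.78. The log2 fold change of FGFBP1 ran from -3.54 to -1.54 over the alternatives, so its size is uncertain, and its call was lost under 1 of them. KRT13 went from 168 ± 116 CPM to 21.2 ± 8.98 CPM, and in naive replicate 3, the library that stood apart, KRT13 was at 302 CPM and MUC6 at 61.7 CPM. In all, 1978 of 13282 genes were called, 752 higher and 1226 lower, and 410 of them changed by at least 1 on the log2 scale, 62 upward and 348 downward. The groups did not overlap for 19.4% of tested genes, where chance gives 2.38%. The count fell to 1219 without released replicate 1, to 1241 without replicate 2 and to 1192 without replicate 5, and to 727 with clone 4 counted as naive. Without naive replicate 3 it was 1455, and the calls of INHBA (adjusted p = 0.102), OLR1 (0.101) and MUC6 (0.054) were lost. Without naive replicate 2 the call of OLR1 was lost as well (0.054).

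**Figure D2:**
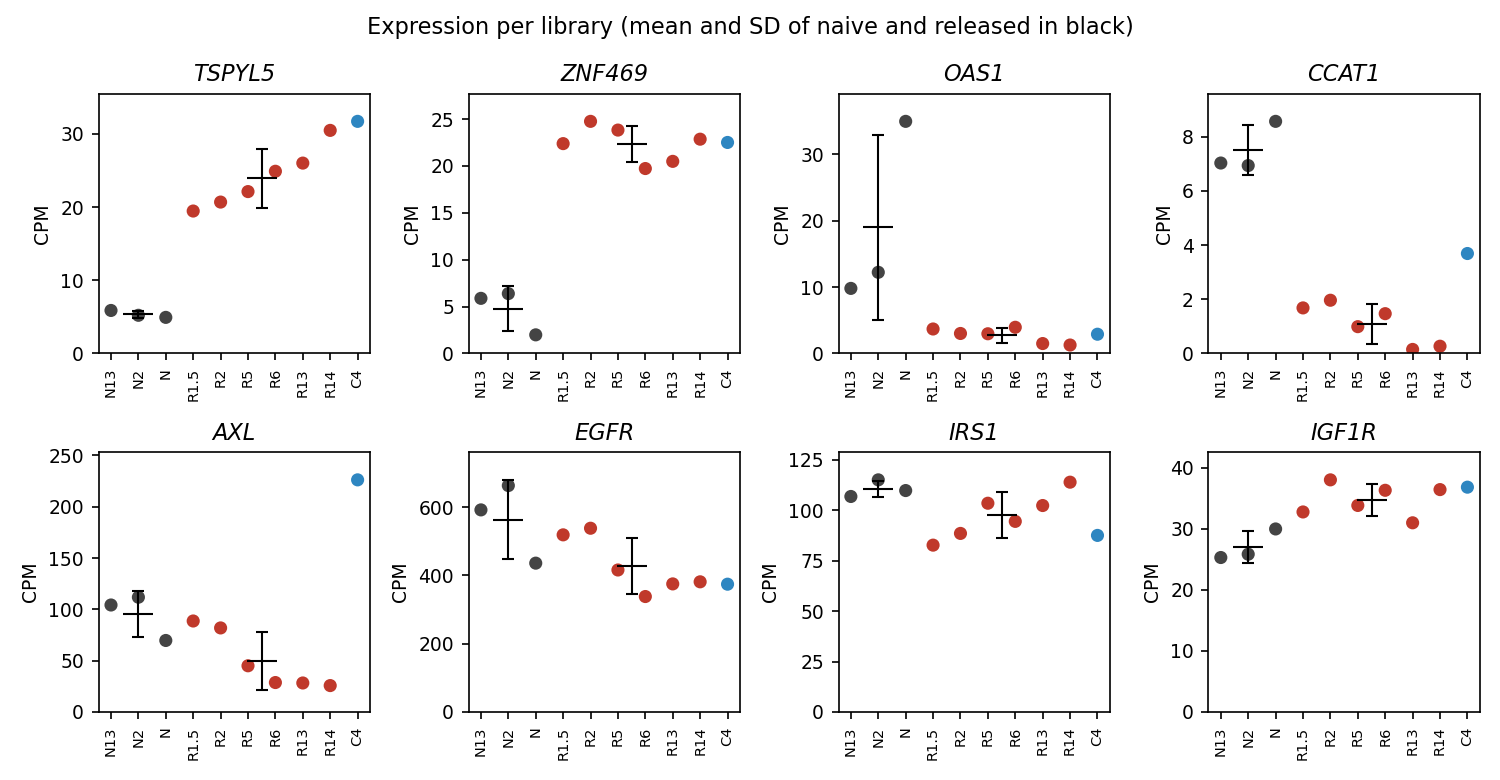
CPM per library (linear axes from 0) for 8 named genes, with naive libraries in grey (N13, N2 and N for 13 weeks, 2 weeks and no week), released libraries in red (R and weeks after release) and clone 4 in blue (C4). Black bars show mean and SD of the 3 naive and 6 released libraries, for example 5.34 and 24.0 CPM for TSPYL5.

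Of 23 tested interferon-induced genes, 9 fell and 1 rose after release (13 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.54 and a camera adjusted p of 2.0e-05. With an estimated correlation the adjusted p = 0.858. OAS1, an antiviral oligoadenylate synthetase, fell most (-2.81, SE 0.42), from 18.99 ± 13.9 to 2.73 ± 1.11 CPM, OASL had -1.79, IFIT1 -1.52 and IFI35 -0.66. USP18, an ISG15-removing protease that restrains interferon signalling, rose by 0.56. OAS1 stood at 34.95 CPM in naive replicate 3. Without that library the list had a camera adjusted p of 0.00019.

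Proliferation genes had a camera adjusted p of 0.0011, with a median of 0.14, and 3 of 35 members rose, none of them when adjusted over the list alone. With an estimated correlation the adjusted p = 0.858. The 3 were RRM2 (0.80, SE 0.23), MCM7 (0.41) and TYMS (0.37), genes of nucleotide supply and DNA replication. RRM2 was 348 ± 33.1 CPM after release against 199 ± 83.6 CPM in naive cells, with 104 CPM in naive replicate 3. The RRM2 call was lost without released replicates 1 (adjusted p = 0.071), 2 (0.070), 3 (0.057), 4 (0.065) or 5 (0.073), and that of MCM7 without replicates 1 (0.058), 2 (0.055) or 5 (0.060). No list was called with an estimated correlation, where 1 of 29 had an unadjusted p under 0.05, and fry called 1, the interferon list. Without released replicate 6 the preset test called 4 lists instead of 2.

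In the insulin and IGF signalling list, 4 of 36 members rose and 4 fell (4 and 4 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.792). IGF2R, the scavenger receptor for IGF2, rose by 0.54 (SE 0.06), from 118 ± 1.06 to 173 ± 9.17 CPM. PIK3R3, a regulatory subunit of PI3 kinase, rose by 0.72, RPS6KB1, the S6 kinase, by 0.42, and IGF1R by 0.35 (SE 0.09, edgeR adjusted p = 0.030). The binding proteins IGFBP3 (-0.74) and IGFBP4 (-0.47), PIK3R1 (-0.59) and FOXO3 (-0.31) fell. IRS1 itself was 111 ± 4.17 CPM in naive and 97.5 ± 11.3 CPM in released libraries (log2 fold change -0.19, SE 0.09, edgeR adjusted p = 0.192), and IRS2 was 159 ± 9.77 and 182 ± 16.7 CPM (0.18, SE 0.09, adjusted p = 0.178). The IGF1R call was lost without naive replicate 1 (adjusted p = 0.088) or 2 (0.087) and without released replicate 2 (0.064), 4 (0.056) or 5 (0.057), in a range of 0.0067 to 0.226 over all alternatives. That of IGFBP3 was lost without released replicates 1 (0.058), 2 (0.057) or 5 (0.056) and without naive replicates 2 (0.061) or 3 (0.171).

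With all released libraries pooled, transcripts of the drug target and its relatives did not pass the test. EGFR was 564 ± 116 CPM in naive and 428 ± 82.0 CPM in released libraries (log2 fold change -0.41, SE 0.16, edgeR adjusted p = 0.115). ERBB2 had -0.14, ERBB3 -0.32, MET 0.30, INSR 0.16 and AXL -0.94, with adjusted p from 0.101 for MET to 0.696 for INSR, and none of the 16 EGFR family and ligand genes was called. Against naive cells by period, EGFR (-0.58, edgeR adjusted p = 0.049) and AXL (-1.82, 0.0023) were lower and MET (0.42, 0.047) was higher at 13 to 14 weeks, and AXL was lower at 5 to 6 weeks (-1.37, 0.014). These calls by period were not refitted with libraries left out, and those of EGFR and MET lay close to the threshold. Of 20 MAPK output genes, 3 fell, namely EPHA2 (-0.49), DUSP5 (-0.66) and PHLDA1 (-0.34), and none rose. Among 13 other receptor kinases and ligands, 3 fell, among them GAS6 (-1.33) and DDR1 (-0.36). Of 18 genes linked to the drug-tolerant state, ALDH1A3 (0.51), ABCG2 (0.78) and EZH2 (0.62) rose and CD44 (-0.56), KDM5B (-0.53) and KLF4 (-0.43) fell. These lists were not called by camera. In the pooled comparison AXL and MET each passed under 2 alternatives. These included leaving out released replicate 3 for AXL (edgeR adjusted p = 0.047) and released replicate 6 for MET (0.034). Over all alternatives the adjusted p ran from 0.0028 to 0.534 for AXL and from 0.0060 to 0.323 for MET. EGFR passed there with the mean of the 3 periods (0.045), for weeks 2 and 13 with week as a block (0.0019) and without naive replicate 3 and released replicate 3 (0.035), an alternative chosen after the data were seen. Over all alternatives the adjusted p of EGFR ran from 0.0019 to 0.344. Calls were lost for DUSP5 without released replicates 1 (0.062), 2 (0.057) or 5 (0.062), and for ALDH1A3 without naive replicates 1 (0.066) or 3 (0.084) or released replicate 5 (0.052).

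The epithelial, lineage and stress lists were not called by camera, and most of their members did not pass the test. Of 26 epithelial genes, 22 did not pass, none rose and 4 fell (5 adjusted over the list alone), among the 4 the serine protease ST14 (-0.59) and the desmosome component PKP3 (-0.41). In the lung lineage list of 13, MUC5AC, HOPX (-2.57) and AGR2 (-1.67) fell and MUC4 rose. In the squamous list of 17, 4 fell, among them KRT13 and KRT5 (-1.70), and TP63, the basal lineage transcription factor, rose by 1.86. The KRT5 call was lost without naive replicate 2 (adjusted p = 0.066). In the neuroendocrine list of 6, with a median of 0.27, 1 gene rose and none fell. Of 23 NRF2 targets, 5 rose and 4 fell, with GCLM, a subunit of the glutathione-synthesis enzyme, at 0.59 and CBR1 at -0.46. Of 28 hypoxia and glycolysis genes, 5 fell and 1 rose, with LDHA at -0.85 (SE 0.13) and HK1 at 0.38. In the unfolded protein response list of 22, EDEM1 (-0.89) and MANF (-0.62) were among 4 falls. None of 23 cholesterol genes was called. The leukocyte list and the fibroblast and endothelial list had 3 tested members each. Summed over all 18 and 13 listed members, they came to 24.3 to 66.5 and 43.1 to 103 CPM over the 10 libraries.

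Genes changed together along stretches of the genome. Over 40 neighbouring genes from BTBD10 to KIF18A the median log2 fold change was -0.58 and 40 of 40 were lower in released cells, 21 of them called. From CMC1 to EIF1B the median was -0.47, with 39 of 40 lower and 22 called. From ZBTB2 to C6orf120 it was 0.41, with 35 of 40 higher and 23 called. Shuffled gene orders reached a largest absolute median of 0.21 in the middle of 1000 shuffles and 0.27 at their 95th percentile. In all, 23 separate windows passed that level, 6 upward and 17 downward, with 7.53% of placed genes. The windows were picked for their fold changes, so the calls inside them are no further test. Several genes named above lie in them: LDHA between BTBD10 and KIF18A, GLB1 (-0.64) between CMC1 and EIF1B, and SOD2 (0.61), IGF2R and OSTCP1 between ZBTB2 and C6orf120. Others in such windows are MANF, CBR1, DDB2, FGFBP1, PKP3, MUC6, MUC5AC, RRM2 and RPS6KB1.

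**Figure D3:**
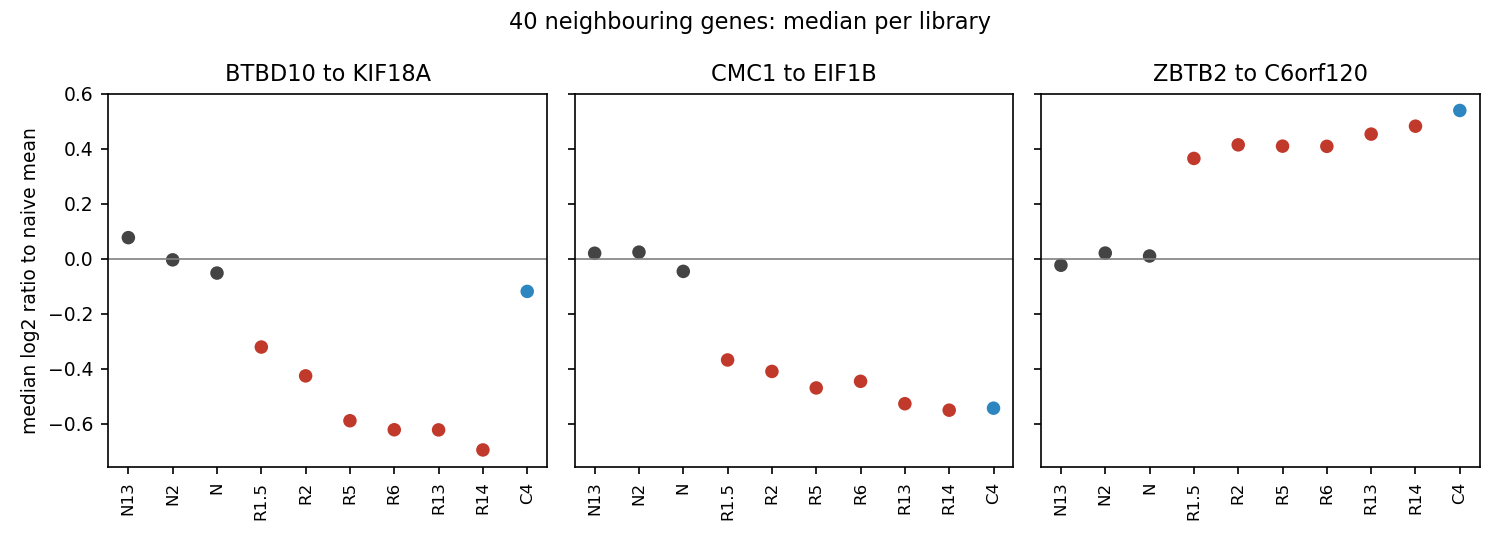
Median log2 ratio to the naive mean over 40 neighbouring genes, per library, for 3 stretches named by their first and last gene (naive grey, released red with weeks after release, clone 4 blue). From BTBD10 to KIF18A the released libraries run from -0.32 at 1.5 weeks to -0.69 at 14 weeks, and clone 4 lies at -0.12; in the other stretches clone 4 lies at -0.54 and 0.54.

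The differences from naive cells were already there early after release and were more numerous late. At 1.5 to 2 weeks, 602 of 13507 genes were called, 231 higher and 371 lower. CDK14, a cyclin-dependent kinase with 10 to 18 counts per naive library, stood at 2.75 (SE 0.30), OLR1 at 3.59, INHBA at 2.38 and the mucin MUC5B at -3.27. At 5 to 6 weeks there were 723 calls (239 higher and 484 lower), with KCNJ12 at 2.14, COL17A1, a hemidesmosome collagen, at -3.11 (SE 0.45). At 13 to 14 weeks there were 1650 (559 higher and 1091 lower), with TSPYL5 at 2.40, the protease PRSS8 at -4.71 and CCAT1 at -5.10, an uncertain size with 2 and 4 counts in the late libraries. Of the early calls, 422 were called late in the same direction, where independent lists would share 39.5. Simulated unchanged groups called 0.30 early and 0.20 late genes on average, too few to give a shared count to compare with. Fold changes correlated across genes at 0.67 between early and late, against 0.39 in simulated unchanged groups with the same naive libraries, and the covariance was 0.213 against 0.0270, a difference of 0.186. In a check chosen after the data were seen, early and late release were set against single naive libraries. With different naive libraries r was 0.31 to 0.57 and the covariance 0.0760 to 0.169 over 6 choices, and with the same one 0.62 to 0.84 and 0.135 to 0.468 over 3, so part of the excess may come from shared controls.

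These counts moved with single libraries. The early count was 4 without released replicate 3, 5 without replicate 4, 186 without replicate 1 or without replicate 2, 256 without replicate 5, 286 without replicate 6 and 1942 without naive replicate 3. The middle count was 53 without released replicate 5, 34 without replicate 6, 339, 343, 312 and 310 without replicates 1, 2, 3 and 4, 449 without naive replicate 2 and 2472 without naive replicate 3. The late count was 221 without released replicate 1, 251 without replicate 2, 1013 without replicate 3, 1009 without replicate 4 and 3401 without naive replicate 3. Where a bin was left with 1 library, that library was assumed to vary like the other groups. Early calls were lost without released replicate 3 or 4 for CDK14 (adjusted p = 0.080 and 0.102), OLR1 (0.172 and 0.160), INHBA (0.144 and 0.116) and MUC5B (0.144 and 0.116). Middle calls were lost for COL17A1 without released replicate 5 (0.096) or 6 (0.089) and for KCNJ12 without replicate 5 (0.082), and the late call of PRSS8 was lost without replicate 1 (0.066) or 2 (0.059). Of the early, middle and late calls, 98.7%, 98.3% and 98.8% kept their call and direction without naive replicate 3.

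Most of the genes called between early and late release were lower late. Of 119 called genes, 107 were lower late and 12 higher. Among the 119, 95 changed by at least 1 on the log2 scale, so this split describes mainly large changes. HLA-B, a class I antigen-presenting molecule, went from 24.0 CPM early to 1.96 CPM late (log2 -3.61, SE 0.54, edgeR adjusted p = 0.022). ANKRD1, a YAP target, went from 8.09 to 0.71 CPM (-3.50), MGP, the matrix Gla protein, from 11.99 to 1.25 CPM (-3.27), and CCAT1 from 1.82 to 0.21 CPM (-3.06). Late libraries had 9 and 11 counts for ANKRD1 and 2 and 4 for CCAT1, so these sizes are uncertain. The receptor kinase AXL went from 85.3 to 27.0 CPM (-1.66) and its ligand GAS6 changed by -1.86, and neither was refitted with libraries left out. MUC5B (2.65), IGFBP2 (0.97) and SPRY1 (0.99) were higher late. Of the 107, 96 were also called lower than naive late and 6 were called above naive early. The count was 0 without released replicate 2 in edgeR, with 1024 genes at an unadjusted p under 0.05, and 2, 6, 24, 53 and 54 without replicates 1, 3, 4, 5 and 6. It was 1633 without naive replicate 3, with 97.5% of the calls kept, and DESeq2 called 326 from all libraries. No naive library enters the difference between late and early itself. Naive replicate 3 can act there only through the shared filter, normalization and estimate of spread. Without released replicate 2 the adjusted p was 0.331 for HLA-B, MUC5B and IGFBP2, 0.335 for SPRY1, 0.275 for ANKRD1 and 0.186 for MGP and CCAT1. Without replicate 3 the same genes ran from 0.087 for MGP to 0.363 for SPRY1, and without replicate 1 from 0.101 for SPRY1 to 0.215 for ANKRD1. Without replicate 4 the calls of CCAT1 (0.081), IGFBP2 (0.081), MUC5B (0.136) and SPRY1 (0.203) were lost. Without replicate 5 or 6 those of HLA-B (0.052 and 0.051), IGFBP2 (0.067 and 0.062) and SPRY1 (0.085 and 0.082) were lost, and MUC5B was at 0.052 without replicate 5 and 0.0501 without naive replicate 3.

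By list, late against early, camera called 7 of 29 lists with a preset correlation and none with an estimated one, and most members of the 7 did not pass the gene test. Ribosomal protein genes had a median of 0.28 (camera adjusted p = 2.0e-11) with 0 of 40 members called, and oxidative phosphorylation genes 0.19 (3.7e-06) with 0 of 30 called. With an estimated correlation the adjusted p = 0.676 for both. Medians below 0 belonged to YAP and TEAD targets (-0.43, preset adjusted p = 1.2e-07, 2 of 20 called lower), antigen presentation (-0.56, 9.1e-07, 2 of 14), interferon response (-0.47, 8.7e-05, 0 of 25), mesenchymal genes (-0.45, 0.0018, 0 of 17) and other receptor kinases (-0.06, 0.039, 2 of 13). With an estimated correlation the adjusted p = 0.489 for each of these, and 2 of 29 lists had an unadjusted p under 0.05. Adjusted over the list alone, 10 YAP and TEAD targets, 10 antigen presentation genes, 6 mesenchymal genes, 5 interferon genes and 4 receptor kinases were lower, 1 receptor kinase was higher, and no ribosomal or oxidative phosphorylation gene was called. Markers of other cells and histone transcripts without a poly(A) tail also differed along these times, as summed CPM per library. At 1.5, 2, 5, 6, 13 and 14 weeks the leukocyte list summed to 35.8, 36.6, 48.6, 50.4, 50.6 and 66.5 CPM, the fibroblast and endothelial list to 43.1, 49.3, 58.9, 71.6, 59.0 and 75.9 CPM, and the histone list, a sign of RNA quality, to 146, 147, 114, 98.0, 103 and 100 CPM. These sums were not tested, and the histone list was not called late against early (median -0.076, camera adjusted p = 0.993). The call of the other receptor kinases was lost without naive replicate 1 (adjusted p = 0.058), naive replicate 3 (0.106) or released replicate 4 (0.111).

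Across the 6 released libraries, over which the marker and histone sums given above also differed, 1018 of 13223 genes followed log2 weeks, 372 upward and 646 downward. The ribosomal protein list had 36 of 40 members rising, with slopes such as 0.12 for RPS20 per doubling of time, and none falling. Its members vary together, with an estimated correlation of 0.939 late against early, so the 36 are not separate observations. TNFSF15, a TNF-family ligand, had the steepest fall at -1.49 per doubling (SE 0.14), followed by HLA-B (-1.33), CST1 (-1.30), BLK, a SRC-family kinase, at -1.29 and ANKRD1 (-1.17). BLK had 1 count in each late library and TNFSF15 8 and 15, so their slopes are uncertain in size. CDH5 (0.54), itself a member of the fibroblast and endothelial list, and the trefoil factor TFF1 (0.43) rose. IRS1 had a slope of 0.11 (edgeR adjusted p = 0.031) and EGFR -0.17 (0.029), and neither slope was refitted under the alternatives. Antigen presentation genes had 9 falling members of 14, and YAP and TEAD targets 10 of 20. The count was 254 with weeks on the linear scale, where 23.6% of the calls were kept, 388 without released replicate 2, 132 without replicate 3, 220 without replicate 4 and 2243 without replicate 6. With 15 weeks for replicate 3 it was 0 in edgeR, with 99 genes at an unadjusted p under 0.05. The calls of CDH5, TFF1 and BLK were lost without released replicate 2 (adjusted p = 0.078, 0.082 and 0.072) or 3 (0.165, 0.102 and 0.309), and that of CDH5 without replicate 4 (0.100).

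The labels call clone 4 an untreated PC9-derived clone and do not say how it was derived or selected. It differed from the naive mean at least 2-fold, and lay outside the range of all other libraries, for 165 genes above and 311 below among 11740. By the same measure, naive replicate 3 set against the other naive libraries had 350 above and 135 below. Naive replicate 1 had 3 above and 13 below, and naive replicate 2 had 13 above and 21 below. A count of this size thus also occurs in the naive library that stood apart, but not in the other naive libraries. The cell adhesion gene CDH13 had the largest log2 ratio at 4.04, followed by the matrix gene TNC (3.40), WNT9A (3.10), KCNJ12 (2.83), HCP5 (2.70) and RASSF2 (2.56). OLFML3 had 3 counts in clone 4 against 111 ± 11.1 CPM in naive libraries, a ratio of 700 with a counting interval of 239 to 3394. OR51B5 and HBE1 had no count and were at least 185-fold and at least 76.0-fold lower, and RNF212 was at least 55.6-fold lower. MUC6 had 3 counts, a ratio of 193 (66.0 to 935), and TFF2 had 1 count.

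By list, the median log2 ratio of clone 4 was 0.70 for cholesterol genes, 0.51 for mesenchymal genes, 0.45 for YAP and TEAD targets, 0.35 for hypoxia and glycolysis genes and 0.30 for proliferation genes, each at the 100th percentile of 10000 random lists. Squamous genes (-1.75), unfolded protein response genes (-0.40) and epithelial genes (-0.31) lay at percentile 0. These percentiles describe 1 library and are no test, since random lists lack the correlation within a list, estimated at 0.771 for cholesterol and 0.361 for proliferation genes in released against naive cells. Hypoxia and glycolysis genes had a median of -0.20 in released against naive cells, and LDHA was 4297 CPM in clone 4, 3841 ± 327 CPM in naive and 2149 ± 355 CPM in released cells. AXL was 226 CPM in clone 4 against 95.3 ± 22.5 CPM in naive cells. Of 1817 genes called between released and naive cells and expressed here, 83.8% had the same sign in clone 4, with r of 0.64 across genes, but both are measured against the same naive libraries. Set against a naive library that was left out of the released fit, the share was 69.6%, 74.4% or 80.6% for naive replicates 1, 2 and 3.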

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

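Among the tests in this part, those of naive replicate 3 and of a single deciding released library were chosen after the results were seen.

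In 6 of 88 sets of values from the released libraries, 1 library lay far from the other 5, where chance flags about 1 in 20 (4.4 expected). The gap to the nearest library, as a fraction of the whole range, was 0.727 for KRT13, 0.718 for DDR1 and 0.765 for RRM2, each at 6 weeks (KRT13 and DDR1 highest, RRM2 lowest). It was 0.679 for FAM167A and 0.733 for BLK, highest at 1.5 weeks, and 0.808 for GLB1, lowest at 13 weeks.

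The effect against naive differed between late and early release, by a test of the difference itself, for CCAT1 (-3.06 log2) and AXL (-1.66) among the 67 named genes. By camera with a preset correlation it differed for 7 lists, with median log2 differences of 0.28 for ribosomal proteins, 0.19 for oxidative phosphorylation, -0.43 for YAP and TEAD targets, -0.56 for antigen presentation, -0.47 for interferon response, -0.45 for mesenchymal genes and -0.059 for other receptor kinases. None of these list calls held with an estimated correlation.

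Of the 84 splits of the 9 libraries into 6 and 3, 1, the real one, called 1978 genes and the highest other called 0. The other splits mix naive and released libraries, which raises the spread within their groups. The real split therefore stands out among these 9 libraries, but a chance difference between cultures cannot be excluded this way. Without naive replicate 3, 60.2% of the called genes were still called in the same direction, which argues against that library alone producing the calls. The pair of libraries at week 2 or at week 13 was also left out. Of the genes then called, 98.7% and 99.2% had the same sign in the left-out pair. Each pair has equal weeks, which argues against time in culture alone. The labels do not say that cultures were independent, so a fixed difference between cultures would give the same agreement. For lists the real split called 2, while 78 of 84 splits called as many and the highest other called 13, so chance cannot be excluded there. A lasting effect of gefitinib, selection of a subpopulation and a fixed difference between cultures all stay open, since the design confounds them.

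The drift with weeks after release may partly be time in culture. Of 1018 trend genes, 83.7% moved the same way from the 2-week to the 13-week naive library, by a median of 0.15 against 0.52 in released libraries over the same weeks (28.8%). That lies between the bounds set in advance, and with 1 naive library per time the contributions cannot be told apart. A single deciding library was tested in a form that was changed 2 times after its values were seen. The first form refitted genes already called (at least 92.0% kept direction at an unadjusted p under 0.05, but 13.0% stayed called without the 1.5-week library), and the next took genes called without a library and asked whether they deviate the predicted way in it, which gave 84.9%, 96.1%, 100% and 100% at 13, 14, 1.5 and 2 weeks but 39.0% at 5 and 75.9% at 6 weeks. The last form dropped the libraries at 5 and 6 weeks, which lie 0.0136 and 0.302 doublings from the mean time of the others and have little predicted deviation, so the test argues against a single deciding library only with that restriction.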

How the results depend on the processing

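Leaving out naive replicate 3 and released replicate 3 together was chosen after the data were seen. Counts stayed within 1.5-fold with size factors and without a filter. Released against naive gave 410 genes with a log2 change of at least 1, 727 with clone 4 as naive, 459 for weeks 2 and 13 without a block, 2202 with week as a block and 1792 without naive replicate 3 and released replicate 3. The size threshold gave 207, 274 and 589 genes for early, middle and late release and 23 for the trend, by construction. DESeq2 gave 1186 for early release and 326 for late against early. The trend gave 254 with linear weeks and 0 with 15 weeks for released replicate 3. Lists of released against naive numbered 0 with an estimated correlation, 1 with fry, 5 with clone 4 as naive and 4 without naive replicate 3 and released replicate 3; late against early gave 0 with an estimated correlation. Apart from the added threshold, the cause of these differences was not tested, and leaving out libraries raised some counts and lowered others.

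With 1 library left out, counts ran from 1192 to 1892 for released against naive, 4 to 1942 early, 34 to 2472 middle, 221 to 3401 late, 0 to 1633 late against early, 132 to 2243 for the trend, 2 to 4 and 6 to 10 for the lists, and 448 to 515 for clone 4. The size threshold of 1 on the log2 scale was not applied to single named genes. Under the other alternatives no called gene named for released against naive changed sign. Of 59 such genes, 13 kept their call under all of these alternatives and 46 lost it under at least 1, 23 of them with 1 library left out. Sign changes came in uncalled genes and in the trend with 15 weeks: INSR -0.060 without naive replicate 1 (range to 0.54 with 1 library left out), ERBB2 0.14 without naive replicate 3 (range from -0.27) and 0.20 without that library and released replicate 3, where ERBB3 was 0.044; and slopes of 0.13 for HLA-B, 0.33 for BLK and 0.000834 for ANKRD1. Over named genes and lists, 945 values kept their side with 1 library left out and 191 lost the call; for other alternatives these were 615 and 122. With 3 naive libraries, changes of 1.5-fold were recovered for 50.7% of simulated genes in released against naive.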

Other observations

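The test of regional sharing was written before its result was seen, as were those of neighbouring genes and of clone 4. The correlations with weeks in this part were chosen after the regions were seen.

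The stretch from BTBD10 to KIF18A moved further with time after release. Its median was -0.32 at 1.5 weeks, -0.43 at 2, -0.59 at 5, -0.62 at 6, -0.62 at 13 and -0.69 at 14 weeks, against 0.08, -0.0041 and -0.05 in the naive libraries. Over the 6 released libraries r with log2 weeks was -0.945 (exact permutation p = 0.0014, adjusted 0.0042 over 3 stretches) and rho was -1 (exact p = 0.0028, adjusted 0.0083), and r was -0.759 without the libraries farthest from the median time. For CMC1 to EIF1B r was -0.971 (exact permutation p = 0.0083, adjusted 0.013) and rho -0.943 (exact p = 0.017, adjusted 0.025), with r of -0.931 without those libraries. For ZBTB2 to C6orf120 r was 0.878 (exact permutation p = 0.035, adjusted 0.035) and rho 0.771 (exact p = 0.103, adjusted 0.103), with r of 0.951 without them. These values rest on 1.5 weeks for released replicate 3. The permutations treat the 6 libraries as independent. The labels do not say that they came from independent cultures, so the p-values may be too small.

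In clone 4 the shifts were larger. From SH3BP2 to HS3ST1 the median log2 ratio was -1.40, with 37 of 40 genes lower, while released cells had -0.28 there. From NUDT16L1 to PDXDC1 it was -0.67 in clone 4 and -0.02 in released cells, and from ANAPC13 to TM4SF1 it was 0.64 and -0.06. From LAMB2 to MANF both were lower, at -0.64 and -0.40.

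A hypothesis is that released cells differ from naive cells partly in genomic regions, as a gain, loss or selected subclone could give. If so, the largest window median should exceed shuffled gene orders. It was 0.581 in size for released against naive, 0.246 for late against early and 1.40 for clone 4, where the 95th percentiles of the shuffles were 0.271, 0.201 and 0.308. The same-sign count of 40 in a window was not reached in 200 shuffles, where the highest was 35. Coordinated regulation of neighbouring genes would give the same, and no DNA was measured, so neither is excluded. The stretches BTBD10 to KIF18A, CMC1 to EIF1B and ZBTB2 to C6orf120 lie on chromosomes 11, 3 and 6. Whether the 23 windows of released against naive gather on a few chromosomes, which bears on this choice, was not tested.

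Released cells and clone 4 may also share some of these regional shifts, and share the direction of single genes, but both comparisons use naive libraries. With a different naive library for each, r over 295 windows ran from 0.294 to 0.586 over 6 choices, where under 0.2 was set in advance as the mark of shared controls and over 0.4 as its opposite. The gene-level share of 69.6% for the least favourable naive library lay likewise between its bounds of 55% and 70%. With different naive libraries, the noise of a single library cannot enter both sides, but a difference common to the naive libraries still can. Shared naive libraries therefore cannot be told apart from a shared origin with these libraries, and how clone 4 was derived or selected is not known.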
